A study of Patiria miniata with 46 samples.

How the data were processed

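Polyadenylated RNA was sequenced from cryosections of arms of young Patiria miniata of 2 specimens. The labels' protocols name full-length PacBio Iso-Seq libraries. Whether the counted reads came from such libraries, or these gave only the transcript models, was not examined. The deposited file holds raw counts per transcript model and library, whole numbers that sum to a different total in each library, as deposited by the authors. The mapping and counting tools, the genome build and any filter on reads are not given in the sources used here. Reads have no molecular identifiers, so intervals and floors cover counting error only.

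The file has 25794 rows and 46 columns of libraries, all used. Each column was matched to a section by the code in its title. Of the rows, 67 carry a gene symbol and 25727 only an assembly identifier. One of the 67 is labelled as overlapping Wnt7 and was left out of the named genes, which leaves 66. The named rows carry another assembly tag (V2) than the others (V4), and it is not known whether some of their reads also belong to an unnamed row. Rows of 1 locus were summed (1925 loci had 2 rows), which gave 23869 loci. The RefSeq gene table of assembly Pmin_3.0 matched 0 of the identifiers, so unnamed loci could not be given names. Of 16 gene lists fixed before the data were examined, only anterior patterning (19 members matched by symbol) and trunk patterning (26 members, of them 13 Hox and 10 Wnt genes) could be matched, with hyphens read as slashes. The other 14 lists were not analysed here.

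The counts were analysed with edgeR 4.0.16 in R 4.3.3. In each axis alone, loci were kept by filterByExpr with a minimum count of 5 and a minimum total of 15, libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit, glmQLFTest) was fitted, with Benjamini-Hochberg adjustment at 0.05. Position was scaled from the first to the last section for the proximo-distal and oral-aboral series. For the left-right series, position and its square were fitted together. The square tested the middle against the edges, and the linear term the slope from section 1 to section 16. A natural spline with 3 degrees of freedom tested for any pattern. Normalised CPM are counts per 1000000 of the TMM-scaled library, and SDs are over the sections named. Standard errors were taken from the fitted change and its F statistic. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Binomial intervals are exact, at 95%.

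The genes named were fixed by rule before the data were examined: in each of the 4 trends the 10 named genes with the smallest p in each direction among those past the threshold, up to 4 called members of each list, and any member of the anterior and trunk lists that passed the low-count filter. Genes named by this rule in 1 trend are also described along the other axes.

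Counts simulated from the real means, with 100 loci changed by a log2 change of 3 and 100 by 1, were used to test the fits. Of the larger changes 100% were recovered in the proximo-distal trend, 93% in the oral-aboral trend, 97% in the left-right midline and 88% in the left-right slope. Of the smaller changes 29%, 9%, 15% and 5% were recovered. The simulated spread was the trend of dispersion with abundance around the spline, not that of each locus. Sections were drawn independently, and all other loci were flat. Where many real loci follow a curve, recovery by a straight line may be lower than these values. No pair of libraries of 1 axis agreed within sampling noise: the smallest chi-square per degree of freedom was 1.43, between proximo-distal sections 15 and 16. The median lag-1 correlation of residuals of neighbouring sections around the trend was 0.119 in the proximo-distal series, against 0.0133 in 1 shuffled order. In the oral-aboral series it was 0.189 against 0.0959. A single shuffled order gives no spread, so it cannot show whether these differences are beyond chance. Correlated residuals can make p-values too small, and curved patterns left in the residuals of a straight line can make them too large. The trend p-values there are therefore approximate.

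Alternatives were DESeq2-style size factors, total count alone, no low-count filter, a stricter one (minimum count 10), DESeq2 1.42.0, limma-trend, groups of sections in place of position, leaving out shallow sections, end sections or each section in turn, and log2 total count as a covariate. Unsummed transcript models, the fit without the locus with the largest share in any 1 section and shifted centres of the left-right slope were added after the data were seen.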

Results

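Arms of the juvenile bat star Patiria miniata, a sea star, were frozen, cut into serial sections and profiled section by section by sequencing of polyadenylated RNA. The 46 libraries form 3 series. The proximo-distal series, along the length of an arm, has 22 sections and the oral-aboral series, from one face of an arm to the other, has 8 sections, both from specimen 1. The left-right series, across the width of an arm, has 16 sections from specimen 2. The comparisons ask where along each axis of an arm each gene was expressed. The labels number the sections but do not say which end of an axis section 1 is, so directions are given by section number. Each position was sampled once, so sections are positions and not replicates, and p-values measure the spread of sections around a trend within 1 arm.

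Total counts ranged from 196002 (section 2) to 680685 (section 17) in the proximo-distal series, from 2573762 (section 6) to 6921408 (section 3) in the oral-aboral series and from 250704 (section 14) to 1591759 (section 8) in the left-right series. Between 14859 and 18912 loci were detected per proximo-distal section, between 21122 and 22499 per oral-aboral section and between 14935 and 20022 per left-right section. A count of 0 allows up to 15.3 CPM (counts per 1000000 counts) in the shallowest proximo-distal section but only 1.17 CPM in the shallowest oral-aboral section. The file names 66 developmental regulators by symbol. All other loci carry only an assembly identifier.

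**Figure D1:**
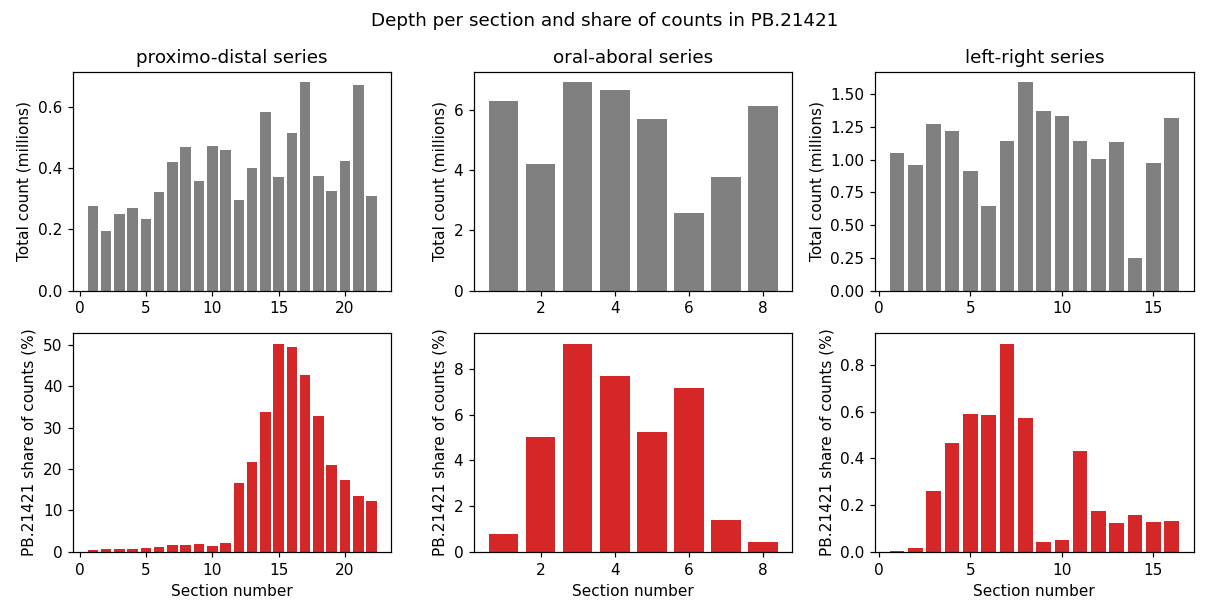
Total count (upper row, grey bars) and percentage of counts in PB.21421, the locus with the largest share in any 1 section (lower row, red bars), per section number, with 1 column of panels per series and separate vertical scales. The locus holds 2.16% of counts in proximo-distal section 11, 16.5% in section 12 and 50.3% in section 15, against at most 9.11% in an oral-aboral section and 0.892% in a left-right section. It was the most abundant locus only in proximo-distal sections 12 to 22 and oral-aboral sections 2 to 6. In the left-right sections other loci led, with 2.61% to 5.51% of counts.

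Along the proximo-distal axis FoxA, a forkhead transcription factor used in endoderm, and Nkx2.2, an NK-class homeobox gene, rose most clearly towards section 22. FoxA stood at 12.6 ± 7.5 normalised CPM in sections 1 to 7 and at 569.4 ± 471 in sections 16 to 22 (SD, n = 7 sections each), and Nkx2.2 at 7.77 ± 6.51 and 224.7 ± 272. Nkx2.1 rose from 63.3 ± 17.6 to 144.2 ± 49.7, the Wnt antagonist Sfrp1-5 from 143.6 ± 37.7 to 274.1 ± 178, and Irx from 88.1 ± 13.7 to 210.3 ± 182. Levels varied widely within the last sections, where FoxA reached 1566 and Nkx2.2 733 normalised CPM in section 22. Irx was no higher in sections 16 to 19 (71.3 to 84.0) than in sections 1 to 7 and rose in sections 20 to 22 alone (234.0, 447.5 and 479.6). Towards the other end, the signalling ligand BMP2-4 fell from 229.7 ± 77.7 in sections 1 to 7 to 92.5 ± 35.6 in sections 16 to 22, the LIM homeobox gene Lhx1-5 from 159.5 ± 48.4 to 56.0 ± 22.6 and the paired-box gene Pax2-5-8 from 127.7 ± 23.8 to 48.2 ± 16.1.

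The fitted log2 change from section 1 to section 22 was 8.13 ± 0.72 for FoxA (SE, edgeR quasi-likelihood adjusted p = 1.96e-09), 9.06 ± 0.89 for Nkx2.2 (adjusted p = 1.06e-08) and 4.67 ± 0.70 for the Wnt receptor Fzd5-8 (adjusted p = 6.52e-06). A straight line describes the first 2 poorly: FoxA did not exceed 22.0 normalised CPM up to section 11 and Nkx2.2 did not exceed 20.8 up to section 15, where sections 8 to 15 averaged 4.95 ± 3.46 (SD, n = 8). Between the means of sections 1 to 7 and 16 to 22 Nkx2.2 rose 28.9-fold. The fitted log2 change was -2.02 ± 0.24 for Pax2-5-8 (adjusted p = 2.15e-07), -2.06 ± 0.28 for Lhx1-5 (adjusted p = 1.28e-06) and -1.86 ± 0.32 for BMP2-4 (adjusted p = 3.99e-05). Nkx6, Hedgehog, Wnt1 and Hox1 also rose, and Tolloid, FGF8-17-18, Wnt3, Pax6, Wnt9, Msx, Wnt10 and Hox5 also fell. Wnt1 was not highest at the end: it peaked at 86.8 normalised CPM in section 18 and had 0 counts in section 22.

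Of the 11 anterior patterning genes tested along this axis, 5 rose (Fzd5-8, Nkx2.1, Sfrp1-5, Irx and Hedgehog), 1 fell (Pax6) and 5 did not pass the test. Of the 19 trunk patterning genes tested, 2 rose (Wnt1 and Hox1), 5 fell (Pax2-5-8, Wnt3, Wnt9, Wnt10 and Hox5) and 12 did not pass. The counts adjusted over the list alone were the same in both lists. Neither list as a whole was shifted in 1 direction against the other genes (limma camera, adjusted p = 0.229 for each).

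Over all loci, 4353 of 11067 tested changed along the axis (edgeR quasi-likelihood test, adjusted p under 0.05), 2244 rising and 2109 falling towards section 22. From section 12 on, 12.2% to 50.3% of all counts came from 1 unnamed locus, V4_HAP1_PB.21421. Scaled by total count alone, 1063 loci rose and 3827 fell, the median locus fell by 0.66 on the log2 scale, and the rises of Sfrp1-5 and Hox1 did not pass (adjusted p = 0.0564 and 0.187), with smaller log2 changes than in the main fit (1.04 and 0.86). The call of Hox1 was also lost without section 21 (adjusted p = 0.0547), without section 22 (adjusted p = 0.0940), without both end sections (adjusted p = 0.156), for sections 1 to 7 against sections 16 to 22 (adjusted p = 0.109) and with limma-trend (adjusted p = 0.0699). That of Wnt1 was lost with limma-trend (adjusted p = 0.0521), and that of Wnt10 without section 1 (adjusted p = 0.0955), without both end sections (adjusted p = 0.195), for sections 1 to 7 against sections 16 to 22 (adjusted p = 0.159) and with log2 total count as a covariate (adjusted p = 0.147). The fitted log2 change without both end sections was 0.79 for Hox1, against 1.32, and -1.27 for Wnt10, against -2.13.

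**Figure D2:**
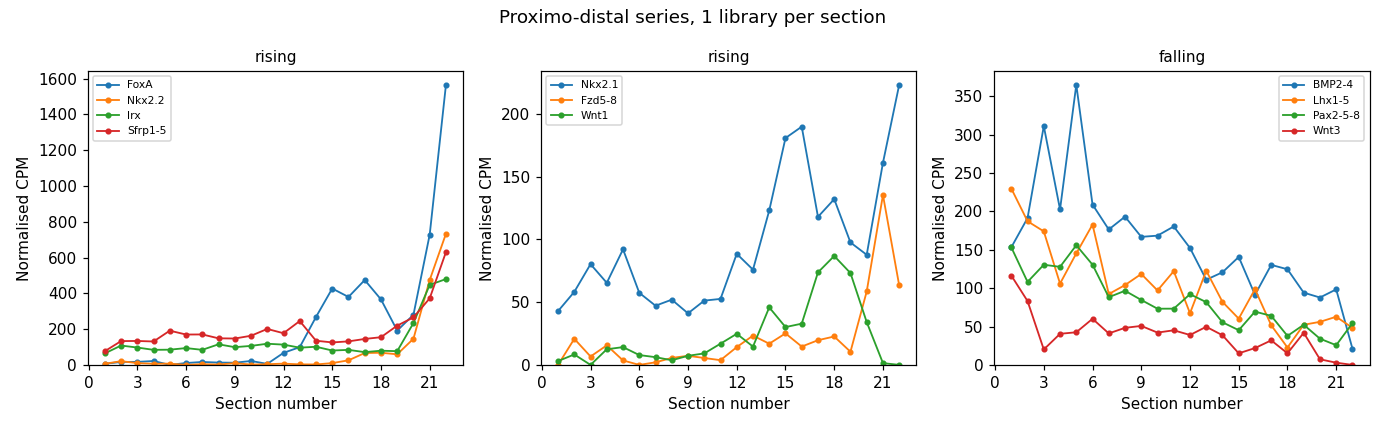
Normalised CPM (vertical axes, separate scales) against proximo-distal section number (horizontal axes) for rising genes (left and middle) and falling genes (right). Each point is 1 library. FoxA reaches 1566 in section 22, and Wnt1 peaks at 86.8 in section 18.

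Across the arm, in the left-right series, many of the named regulators were concentrated in the middle. Otx, a homeobox gene of anterior and neural territories, had 0 counts in sections 1 to 6 and 14 to 16 and 441 counts in the 7 sections between, peaking at 93.1 normalised CPM in section 9. Dmbx had the same range of sections, with a peak of 89.3 in section 9. The 6 central sections (6 to 11) averaged 44.6 ± 34.2 for Otx against 3.44 ± 7.43 in the 10 outer sections (SD), 35.98 ± 32.8 against 4.42 ± 9.38 for Dmbx, 42.4 ± 28.4 against 10.0 ± 15.1 for Pax6 and 29.01 ± 19.4 against 3.79 ± 4.54 for the signalling ligand Hedgehog. FoxA was 5.06-fold and Fzd5-8 10.1-fold higher in the central sections. All 6 passed the midline test (edgeR quasi-likelihood adjusted p from 1.88e-08 for Otx to 6.25e-06 for Pax6). Fitted log2 values for genes with empty edges depend on the model and are not given.

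Of the 14 anterior patterning genes tested across the arm, 9 were higher in the middle (Otx, Dmbx, Hedgehog, Fzd5-8, Pax6, Sfrp1-5, FoxG, Six3-6 and BarH1), 1 was higher at the edges (Otp) and 4 did not pass. Adjusted over the list alone, 11 were higher in the middle and 1 at the edges. The list as a whole was higher in the middle than other genes (camera with a preset correlation, adjusted p = 0.000165), but not with an estimated correlation (adjusted p = 0.0696).

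Of the 9 Wnt genes tested, which belong to the trunk list, 7 were higher in the middle (Wnt1, Wnt4, Wnt5, Wnt6, Wnt7, Wnt10 and Wnt16) and 2 did not pass. Wnt4 averaged 38.7 ± 22.7 normalised CPM in the central sections against 2.63 ± 2.95 outside, Wnt1 31.6 ± 14.4 against 3.91 ± 2.92 and Wnt6 26.8 ± 10.7 against 3.20 ± 3.23. Wnt16 had 97 counts in the central sections and 2 outside. Wnt7 was 5.32-fold higher in the middle, but a second row of the file is labelled as overlapping Wnt7, so its reads may be divided between rows. Of the 9 Hox genes tested, also on that list, 3 were higher in the middle (Hox8, Hox9-10 and Hox7) and 4 at the edges (Hox11-13d, Hox1, Hox5 and Hox4). Hox8 averaged 52.3 ± 21.7 in the central sections against 10.2 ± 8.65 outside, whereas Hox11-13d averaged 22.5 ± 9.38 against 79.5 ± 25.6 and Hox5 30.3 ± 14.3 against 69.1 ± 13.6. Pax2-5-8 was also higher at the edges, at 118.8 ± 32.2 against 56.6 ± 17.2. The trunk list as a whole was not shifted in 1 direction against other genes (camera with a preset correlation, adjusted p = 0.177). Its members moved both ways: of 21 tested, 10 were higher in the middle and 5 at the edges. Over all loci, 3605 of 16523 passed in either direction.

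Over all loci, 3605 of 16523 tested passed the midline test, 2125 higher in the middle and 1480 higher at the edges. The median locus was 0.12 higher in the middle on the log2 scale. Scaled by total count alone the median was 0.49 higher and 4190 loci were called higher in the middle and 737 at the edges, and the edge-high calls of Hox4, Otp, Msx and Lhx1-5 did not pass (adjusted p = 0.0921, 0.145, 0.0715 and 0.378). Some calls lay near the threshold: in the 16 fits that each left out 1 section, BarH1 kept its call in 13, Six3-6 and Hox4 in 12, Hox9-10 in 11, Otp in 10 and Hox7 in 5, with adjusted p up to 0.0815 for BarH1 (without section 16), 0.0680 for Six3-6 (without section 16), 0.0932 for Hox4 (without section 16), 0.0633 for Hox9-10 (without section 7), 0.215 for Otp (without section 1) and 0.115 for Hox7 (without section 1). The fitted changes in these fits were not tabulated. Other alternatives ended some of these calls too. With limma-trend 7 anterior genes were higher in the middle, without Six3-6 and BarH1 (adjusted p = 0.0731 and 0.0734). BarH1 was also not called for the 6 central against the 10 outer sections (adjusted p = 0.0801) or without both end sections (adjusted p = 0.191), Six3-6 with log2 total count as a covariate (adjusted p = 0.0521), Hox9-10 for central against outer sections (adjusted p = 0.116), and Hox4 and Otp without both end sections (adjusted p = 0.157 and 0.151). Otp also lost its call with no low-count filter (adjusted p = 0.0520) and with the covariate (adjusted p = 0.05004), and Hox7 in 6 alternatives (adjusted p from 0.0502 to 0.120). Several of these calls ended with little loss of the fitted log2 difference: Otp had -1.10 without the filter, -1.09 with the covariate, against -1.11, and a larger one without both end sections, Hox4 -1.29 without both end sections, against -1.21, and Hox7 1.61 with limma-trend and 1.90 to 2.37 in the other 5, against 1.94. The difference was smaller for BarH1 without both end sections and for Six3-6 with the covariate (1.51, against 1.71).

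**Figure D3:**
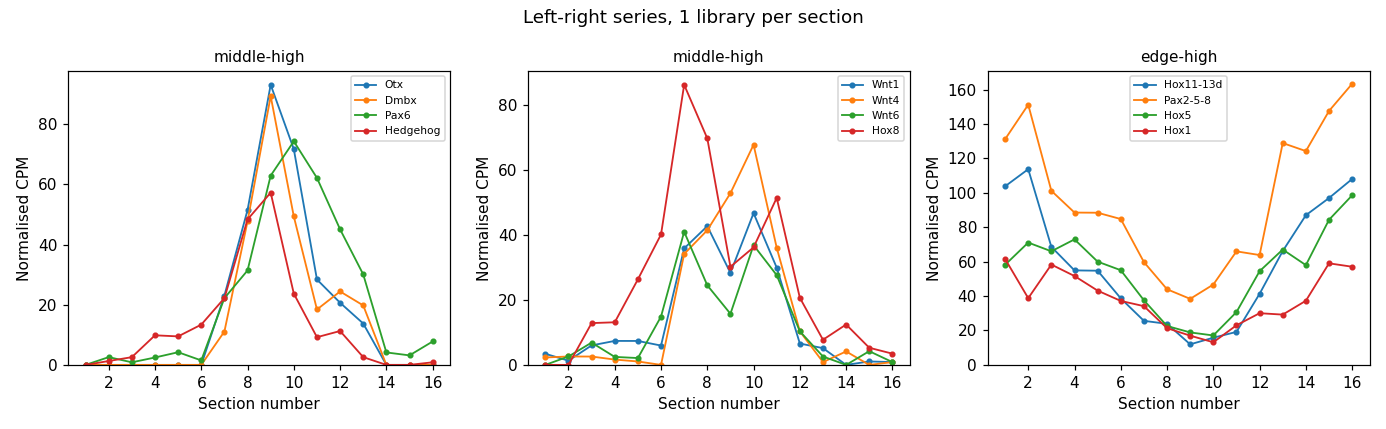
Normalised CPM (vertical axes, separate scales) against left-right section number (horizontal axes) for genes higher in the middle (left and middle) and higher at the edges (right). Each point is 1 library. Otx and Dmbx peak at 93.1 and 89.3 in section 9, and Hox11-13d reaches 113.7 in section 2.

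Fewer loci had a slope across the arm, fitted beside the midline term. Of 16523 loci, 177 passed (edgeR quasi-likelihood test, adjusted p under 0.05), 152 with a positive slope, towards section 16, and 25 with a negative one. The slope was positive for Otx, Pax6, Dmbx and Tailless (adjusted p = 0.000812, 0.00150, 0.00154 and 0.00613) and negative for BMP2-4 (adjusted p = 0.0304). Otx, Dmbx and Tailless did not rise to section 16: their counts lay in sections 7 to 13 alone, so they averaged 0 in sections 1 to 5 and 6.88 ± 9.73, 8.83 ± 12.2 and 2.83 ± 4.22 normalised CPM in sections 12 to 16. BMP2-4 averaged 82.0 ± 17.0 normalised CPM in sections 1 to 5 and 40.7 ± 11.1 in sections 12 to 16 (SD, n = 5 sections each), and Pax6 2.02 ± 1.64 and 18.0 ± 18.7. These calls depended on the test: limma-trend called 52 loci and none of the 5 named genes (adjusted p = 0.580 for Otx, 0.165 for Pax6, 0.543 for Dmbx, 0.534 for Tailless and 0.0660 for BMP2-4), and the DESeq2 Wald test did not call Otx or Dmbx (adjusted p = 0.606 and 0.553). BMP2-4 kept its call in 8 of the 16 fits that each left out 1 section, with an adjusted p of up to 0.107 (without section 16), and lost it with the centre moved to the fitted plane of symmetry (adjusted p = 0.0584), where its fitted log2 change was -1.17, against -1.26 ± 0.28 (SE) in the main fit. With limma-trend the change of BMP2-4 was -1.22, while that of Pax6 was 2.75, against 6.06 ± 0.94 (SE). Those of Otx, Dmbx and Tailless were also smaller with limma-trend.

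Along the oral-aboral axis a straight line from one face to the other called few loci. Emx, a homeobox gene, fell from 107.8 ± 65.8 normalised CPM in sections 1 and 2 (154.3 and 61.3) to 7.83 ± 1.85 in sections 7 and 8 (SD, n = 2). Pax6 fell from 17.6 ± 3.53 in sections 1 and 2 to 0.715 ± 0.713 in sections 7 and 8. BMP2-4 rose from 42.2 ± 10.3 to 122.7 ± 26.8. The fitted log2 change from section 1 to section 8 was -3.89 ± 0.53 for Emx (SE, edgeR quasi-likelihood adjusted p = 0.0178), -6.33 ± 1.06 for Pax6 (adjusted p = 0.0452) and 1.73 ± 0.29 for BMP2-4 (adjusted p = 0.0468). Over all loci 149 of 19769 passed, 136 rising and 13 falling. This number was unstable, with 599 loci by the DESeq2 Wald test and 63 to 362 when 1 section was left out. It was 0 for sections 1 to 3 against sections 6 to 8 with edgeR. In that last fit 1438 of 19769 loci had an unadjusted p under 0.05, which a share of 0.05 of unchanged loci has by chance. Since 9% of simulated log2 changes of 1 were recovered, the number called does not show that few genes changed. Of 17 anterior patterning genes tested 2 fell (Emx and Pax6) and 15 did not pass, and 3 fell when adjusted over the list alone. Of 25 trunk patterning genes 0 passed with edgeR and 0 with limma-trend, although 6 had an unadjusted p under 0.05, while the DESeq2 Wald test called 4. Adjusted over the list alone, 1 trunk gene rose. The anterior list fell as a whole with a preset correlation (camera adjusted p = 0.00360) but not with an estimated one (adjusted p = 0.309), and the trunk list did not (adjusted p = 0.685). These calls lay near the threshold. Emx lost its call without section 1, 7 or 8 (adjusted p = 0.0520, 0.0701 and 0.0928). Of the 8 fits that each left out 1 section, Pax6 kept its call in 1, without section 1 (adjusted p from 0.0661 to 0.251 in the others), and BMP2-4 in 0 (adjusted p from 0.0826 to 0.172). Without both end sections none of the 3 passed (adjusted p = 0.323, 0.0884 and 0.288), with a smaller fitted change for Emx (-2.87) and larger ones for Pax6 (-7.36) and BMP2-4 (1.94).

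A flexible curve called many more loci along the oral-aboral series than the straight line. Over all loci 8722 of 19769 departed from a flat line, and the fitted peak lay in sections 3 to 6 for 4266 of them, in sections 7 and 8 for 3056 and in sections 1 and 2 for 1400. FoxA averaged 511.6 ± 30.0 normalised CPM in sections 3 to 6 against 73.8 ± 82.6 in the 4 outer sections (adjusted p = 0.00121), Nkx2.2 175.2 ± 49.6 against 12.6 ± 14.9, Hedgehog 49.6 ± 14.6 against 4.42 ± 3.69 and Fzd5-8 52.3 ± 23.7 against 3.35 ± 3.42. Otx had 235 counts, 0 of them in sections 7 and 8, and peaked at 15.0 in section 3. Hox11-13b and Hox11-13d were high in sections 7 and 8 instead, at 73.5 ± 13.7 and 101.5 ± 24.7, against 6.13 ± 3.30 and 22.2 ± 8.67 in sections 1 and 2. Of the 17 anterior genes 14 passed, 10 with a peak in sections 3 to 6, 4 in sections 1 and 2 and 0 in sections 7 and 8. Of the 25 trunk genes 18 passed, with 11, 2 and 5 peaks in those ranges. The same test called 5907 of 11067 loci along the proximo-distal axis and 4227 of 16523 across the left-right axis.

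**Figure D4:**
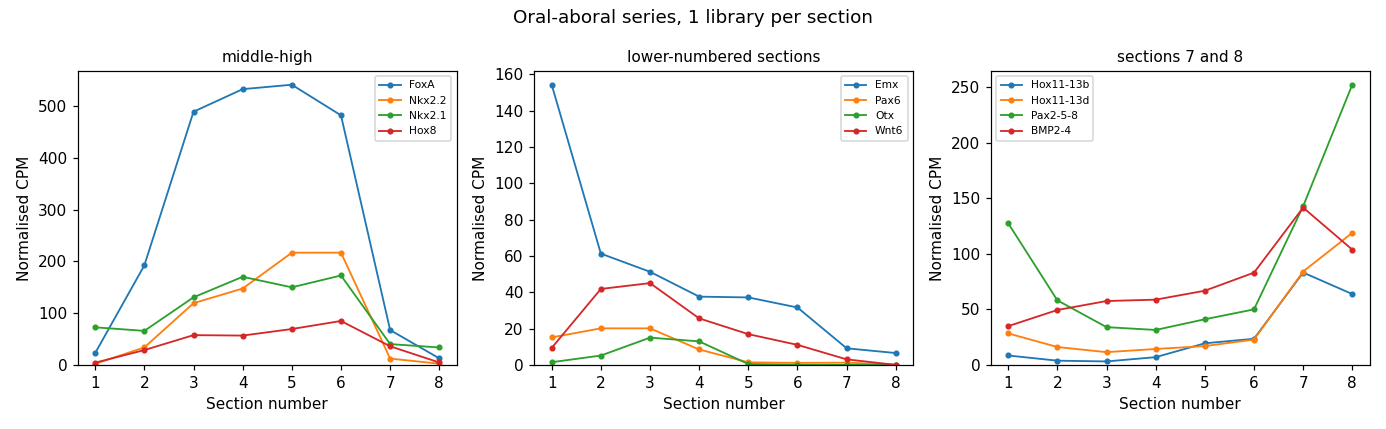
Normalised CPM (vertical axes, separate scales) against oral-aboral section number (horizontal axes) for genes high in the middle sections (left), in the lower-numbered sections (middle) and in sections 7 and 8 (right). Each point is 1 library. FoxA averages 511.6 in sections 3 to 6, Emx is 154.3 in section 1 and Hox11-13d averages 101.5 in sections 7 and 8.

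The axes were compared gene by gene, since they were cut from different arms in different planes. The overlaps below use the oral-aboral trend list, which was unstable as described above (149 loci, and 0 to 599 in the alternatives), and were not repeated with other versions of it. Across 16060 genes tested on both, the midline effect and the oral-aboral trend were weakly opposed (Spearman rho = -0.157, across genes, which are not independent replicates). Among the 3549 genes called on at least 1 of these axes, rho was -0.351. Of 123 genes that rose towards oral-aboral section 8, 81 were higher at the left-right edges, against 11.0 for independent lists (odds ratio 20.8, Fisher's exact test, two-sided, p = 5.07e-55, adjusted p = 4.06e-54 over 8 overlaps). The p-values of these overlaps also take genes as independent. They can be too small where genes vary together, and they measure no spread between arms. Of the 11 genes that fell, 5 were higher in the middle, against 1.42 (odds ratio 5.63, adjusted p = 0.0169). The proximo-distal and oral-aboral trends showed almost no correlation (rho = 0.00998, 11056 genes, and -0.0131 among the 4424 called on at least 1 axis). Genes rising towards oral-aboral section 8 were under-represented among those rising along the proximo-distal axis (7 against 16.2 for independent lists, adjusted p = 0.0169) and among those falling along it (4 against 15.2, adjusted p = 0.00195).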

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

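The tests of library size, of PB.21421 and of the left-right centre in this part were chosen after the results were seen. The shuffles of section order were planned.

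In the oral-aboral series, Emx stood at 154.3 normalised CPM in section 1, and the nearest section had 61.3, a gap of 0.629 of the whole range, above the 95% critical value of Dixon's test for 8 values. This was 1 of 20 values examined in that series, and chance gives about 1 in 20. The sections are positions along a gradient, so a high first section is also what a steep trend gives.

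In the proximo-distal series, 4353 loci changed while 1 locus, PB.21421, rose from 2.16% of counts in section 11 (exact 95% interval 2.12% to 2.204%) to 16.5% in section 12 and 50.3% in section 15. With that locus left out of the data, 4297 loci were called, 4219 of them the same in the same direction. TMM sets aside loci with extreme ratios, so this fit could change little. Scaled by total count alone, 4890 were called, 3172 of them the same. With log2 total count as a covariate 3146 were called, 2983 of them the same. That total includes the counts of PB.21421, so it does not measure the depth left for the other loci. The test therefore cannot settle how far depth contributes. Of 100 orders of the sections, the real one included, 1 gave as many calls for the trend and 1 for any pattern, and the highest of the others gave 0 and 321 (real value 5907 for any pattern). The calls thus depended on the order of the sections. Shuffling also removes any correlation of neighbouring sections, so it cannot tell position from any other gradual change along the series. Position along the arm stays open as an untested biological explanation, in 1 arm.

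Across the left-right series, 177 loci were called on the slope. The plane of symmetry fitted from all 3605 genes called on the midline lay at section 8.80, against 8.50 for the middle of the series. With the centre moved there, 156 loci were still called on the slope, 138 of them the same. Of 17 centres tried from section 6.5 to 10.5, none called fewer than 155 loci (at section 8.75, 141 of them the same). Of the 177 loci, 91 were still called at section 9.5, 70 at section 10 and 59 at section 10.5, against 139 at section 6.5. The totals called at these centres were 200, 420, 863 and 2396, so moving the centre also added new calls. The lowest total therefore cannot settle how far an off-centre series contributes to the 177 calls. With log2 total count as a covariate 215 were called, 171 of them the same. Of 100 orders 3 gave as many calls, and the highest of the others gave 556, which points to a structure of the sections. Since limma-trend called 52, a difference between the sides is open.

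The other shuffles were as follows. For the left-right midline 1 of 100 orders gave as many calls (real 3605, highest other 242), and for any pattern across that axis 1 (real 4227, highest other 155). For any pattern along the oral-aboral axis 1 of 100 gave as many (real 8722, highest other 2). For the oral-aboral trend 3 of 100 did (real 149), and the highest other order called 4122 loci, which points to a structure of the sections. A curve for middle against outer sections, chosen after the results were seen, called 10146 of 19769 loci in this series. Which sections the order with 4122 calls placed at its ends was not examined.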

How the results depend on the processing

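The fits with unsummed transcript models, without PB.21421 and with shifted centres of the left-right slope were chosen after seeing the data. No paired analysis was possible because section numbers shared between series are positions along different axes and arms. The proximo-distal trend stayed within 1.5 times its count in all 11 alternatives (3146 to 6023 loci), the left-right midline in all 13 (2414 to 4927) and any pattern along each axis in all 7. The directions of these calls depended more on the scaling. With total count alone, 1063 loci rose and 3827 fell along the proximo-distal axis, against 2244 and 2109, with 3172 calls shared. For the midline, 4190 were higher in the middle and 737 at the edges, against 2125 and 1480, with 2862 shared. The left-right slope (177) gave 284 loci scaled by total count alone and 52 with limma-trend. The oral-aboral trend (149) gave 599 with the DESeq2 Wald test, 82 without the first and the last section and 93 with log2 total count as a covariate. It gave 0 for sections 1 to 3 against sections 6 to 8 with edgeR. There 1438 of 19769 loci had an unadjusted p under 0.05, which a share of 0.05 of unchanged loci has by chance. The causes were not tested. Scaled by total count alone, the split of the oral-aboral trend was 112 rising and 34 falling, against 136 and 13. With fewer genes, those called on at least 1 axis, the correlation of the midline with the oral-aboral trend was -0.351 and that of the proximo-distal with the oral-aboral trend turned to -0.0131. Of 8 list tests 2 passed with a preset and 0 with an estimated correlation. Leaving out each section in turn gave 3953 to 4329 loci for the proximo-distal trend, 2733 to 3762 for the left-right midline, 122 to 214 for the left-right slope and 63 to 362 for the oral-aboral trend, which had 362 without section 1, 63 without section 2, 87 without section 3, 95 without section 4, 97 without section 5, 76 without section 7 and 66 without section 8. Among called named genes no alternative turned a direction. The proximo-distal calls held in 216 of 225 combinations of gene and alternative, the midline calls in 421 of 455, the slope calls in 53 of 64 and the oral-aboral calls in 22 of 33. No proximo-distal or oral-aboral section was as shallow as the planned limit on total count, so the alternative without shallow sections was not run there. A count of 0 allows the highest level in the proximo-distal series (15.3 CPM in its shallowest section).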

Other observations

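All tests in this part were chosen after the results were seen.

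A curve for middle against outer sections of the oral-aboral series called 10146 of 19769 loci, 5418 higher in the middle sections and 4728 higher at the outer ones, with 30 named genes in the first set and 10 in the second (edgeR quasi-likelihood test). Genes that rose towards proximo-distal section 22 were concentrated in the first set: 1534 of 2244 were higher in the oral-aboral middle, against 588 for independent lists, while of the 2104 that fell 54 were, and 1285 were higher in the outer sections. Across the left-right series, 1045 of the 2075 midline-high genes were higher in the oral-aboral middle, against 543 for independent lists. The series were cut from different arms, genes are not independent replicates, and the reason for these overlaps was not tested.

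Genes higher at the left-right midline had a median oral-aboral log2 change of -0.18, and edge-high genes one of 0.25, a difference of -0.43. If low-numbered oral-aboral sections lay nearer the groove side of the arm, the difference was required to lie below -0.5, and a value above 0 would have argued against it. The value lies between. Both limits were set by choice and not from the spread of the values, so a value between them decides nothing. The question of which face section 1 belongs to stays open.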
